A study of Mus musculus with 12 samples.

How the data were processed

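Primary sympathetic neurons from the superior cervical ganglia of postnatal day 6 CD1 mice were grown for 6 days in vitro before treatment. They were transduced with lentiviral vectors carrying a non-targeting control shRNA (shCtrl) or an shRNA against PML (shPML) for 3 days, and then mock treated or given 600 IU/ml of interferon alpha (IFNα) for 18 h. Total RNA came from about 50000 neurons per extraction, and the libraries were not stranded, per the labels' protocols. The 4 groups hold 3 libraries each, and the groups and replicate numbers were taken from the sample titles. The labels do not say that replicates are separate cultures, so p-values measure only the spread between these libraries, which may be technical. Before averaging, the counts of each pair of replicates were compared by a chi-square test over genes with at least 20 counts in the pair. Every pair differed by more than sampling noise, so each library was counted as 1 replicate.

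The authors deposited, for each library, a table of whole-number counts per gene as STAR writes it. They also deposited a table of expected counts and TPM per gene as RSEM writes it. FastQC 0.11.8, STAR 2.7.1a and RSEM 1.3.1 are listed in the submitters' processing notes, with no role given. The deposited counts are not normalized. The deposited expected counts are RSEM's estimated read numbers, not scaled for depth or length, and RSEM shares out reads that match several places. The deposited TPM values are scaled to a fixed total per library and were not used in any test. The genome build is not given in the sources used here. The files list 55573 gene identifiers. GENCODE M21 (GRCm38) gave gene symbols for 55094 of them by the full identifier and for 300 more without the version number. The other 179, which held at most 0.0266% of a library's counts, kept their identifiers. Coordinates are those of GENCODE M21 on GRCm38, matched by gene identifier.

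The unstranded column of the STAR tables was used, since the counts in its strand-specific columns differed by a ratio of at most 1.011. Totals over genes were 17360018 to 24242121 counts per library. Of all reads, 57.36 to 71.36% were assigned to genes. The lines that name no gene were left out of library sizes and tests. They held 7.51 to 15.21% of reads (unmapped), 5.6 to 7.85% (mapped to several places), 6.04 to 11.01% (outside genes) and 7.6 to 10.82% (in overlapping genes). STAR counts a read only where it maps to a single place and overlaps a single gene, so genes with near-identical copies and overlapping or antisense genes are undercounted or uncertain. Floors and ratios of counts cover counting error only.

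Genes were tested with the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) on the deposited counts. Low-count genes were removed with filterByExpr, which left 14934 genes. TMM scaling was used, the fit was robust, and all 12 libraries entered 1 fit of 4 group means with 8 residual degrees of freedom. The common biological coefficient of variation was 0.165. The 5 contrasts were: IFNα against mock with each shRNA, shPML against shCtrl in each treatment, and their interaction, which is the IFNα effect in shPML minus that in shCtrl neurons. Adjusted p-values are Benjamini-Hochberg values over the genes tested in a contrast, and a gene was called at an adjusted p under 0.05. The SE of a log2 fold change is the unshrunk change divided by the square root of F. CPM are counts relative to the TMM-scaled library size, and values are mean ± SD over 3 libraries. Where a group held no count, the fold was computed against a floor of 3 counts over the group and is given as a lower bound. Where a group held 1 to 3 counts, levels are given and no fold.

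The size of the interferon response was measured over genes that rose at least 2-fold on average over both shRNAs and passed the test of that average. Their interaction was summarised as a median. A list score, the mean log2 CPM (prior count 2) of the antiviral list in each library, was compared between shRNAs by exact permutation tests, two-sided. Overlaps of calls were set beside the number that independent lists would share, since the contrasts compared this way hold no library in common.

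Gene lists were tested with camera in edgeR (two-sided, inter-gene correlation preset at 0.01, Benjamini-Hochberg over lists within a contrast), and again with the correlation estimated. The number of members called over all genes is given, and where it differs the number adjusted over the list alone. The 21 lists were interferon-stimulated antiviral genes, interferon signalling, PML nuclear body, antigen presentation, interferon-inducible GTPases, nucleic acid sensing, chemokines and inflammation, interferon genes, p53 targets, unfolded protein and integrated stress response, immediate early genes, axon injury and regeneration, cholesterol synthesis, sympathetic neuron identity, pan-neuronal genes, glia markers, fibroblast and mural markers, endothelial markers, immune cell markers, cell cycle, and mitochondrially encoded genes. Lists overlap: 6 of the 24 nucleic acid sensing genes and 4 of the 18 axon injury genes are in another list. The symbols Ifgga2, Ifgga3, Mb21d1 and Sting1 matched no gene of the files. Samples, tests, lists and most other settings were fixed before the data were examined. So was the rule for named genes. It takes Pml, then up to 4 called members of each list with the largest change (or its most counted member where none was called). It adds the 5 genes with the largest rise and the 5 with the largest fall among called genes that reach 1 CPM in a compared group and whose 3 libraries of the 2 groups do not overlap. Genes named in an earlier contrast may be given again.

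The other settings chosen in advance were RSEM expected counts rounded to whole numbers, the size factors of DESeq2 in edgeR, no low-count filter, the Wald test of DESeq2 1.42.0, the replicate number as a block, a fit of only the 6 libraries compared, and each library left out in turn. After the data were examined, a split of 4 libraries from the other 8 was added as a term in the fit, and the tests were repeated on the 8.

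For a search of short sequence motifs, the longest annotated 3′ UTR of each of 12211 genes with at least 50 bases of 3′ UTR and a mean of at least 1 CPM was taken from GENCODE M21. Each of the 16384 possible 7-base sequences was scored by a rank-sum z of the log2 fold changes of genes with and without it, adjusted for UTR length, GC content and expression level, and set beside the extremes of 200 shuffles of the fold changes. Of the 1211 genes called between the shRNAs in either treatment, 1159 (95.7%) were searched.

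The tests were run first on simulated counts drawn from the real means and library sizes. With 200 genes changed, the share of 2-fold changes called was 68.7% for IFNα in shCtrl, 70.1% for IFNα in shPML, 68.7% for shPML in mock, 76.1% for shPML in IFNα and 47.8% for the interaction. For 1.5-fold changes these shares were 31.3, 34.3, 44.8, 41.8 and 14.9%. Camera found 5 of 5 simulated lists raised 1.5-fold and called 0 of 15 unchanged lists. Genes were drawn independently of each other and without the split of 4 libraries. These results therefore do not show how the tests behave where genes move together. A planted 7-base sequence was found, and none was called where none was planted. The motif search and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.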

Results

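Gene expression was measured by RNA sequencing in 12 libraries of cultured mouse sympathetic neurons, 3 in each of 4 groups. Neurons carried a control or a PML shRNA and were mock treated or given IFNα, a type I interferon that induces antiviral genes through its receptor and the STAT1, STAT2 and IRF9 complex. PML is the scaffold protein of PML nuclear bodies and is itself induced by interferon. The title of the series asks what part PML takes in the induction of interferon-stimulated genes in these neurons. Library totals over genes ran from 17360018 counts (mock-treated shPML replicate 2) to 24242121 (IFNα-treated shPML replicate 1), and 18932 to 20437 genes had at least 1 count.

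Pml transcripts fell with the PML shRNA in both treatments. The gene (ENSMUSG00000036986.16) lies on the minus strand of chromosome 9 from 58218076 to 58249786. Its level was 11.4 ± 2.24 CPM in mock-treated shCtrl neurons and 4.19 ± 0.667 CPM in mock-treated shPML neurons (SD, n = 3 each). After IFNα it was 43.6 ± 7.35 CPM with shCtrl and 15.6 ± 2.47 CPM with shPML (SD, n = 3 each). The PML shRNA left 36.8% of the transcript in mock-treated neurons (log2 fold change −1.44 ± 0.19 SE, adjusted p = 0.000405) and 35.9% after IFNα (−1.48 ± 0.18 SE, adjusted p = 0.000203), and all 3 libraries lay below all 3 controls in each treatment. IFNα raised Pml 3.82-fold with shCtrl and 3.72-fold with shPML, so that IFNα-treated shPML neurons held 137% of the level in mock-treated shCtrl neurons.

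**Figure D1:**
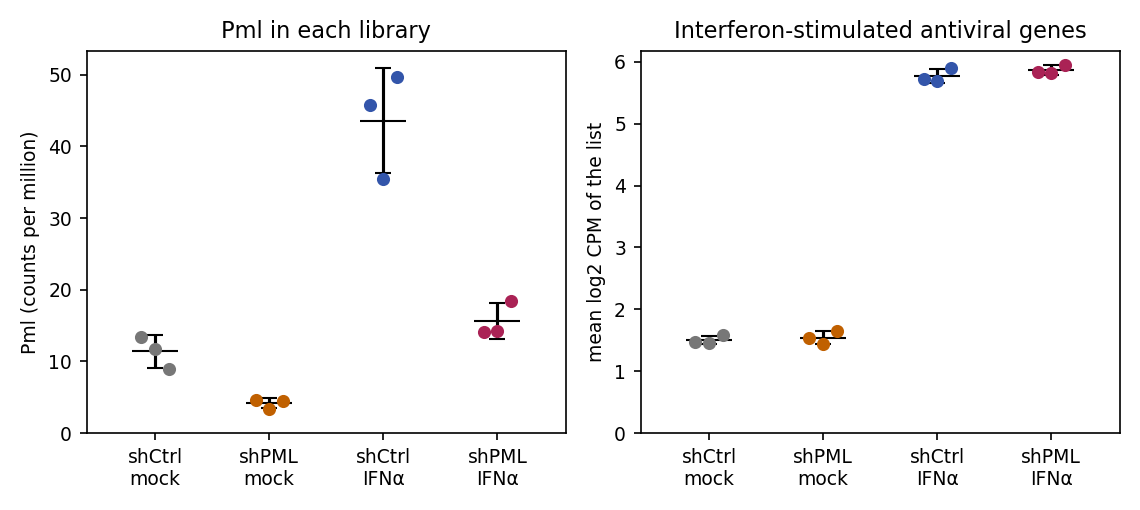
Left, Pml in CPM for each library; right, mean log2 CPM of the interferon-stimulated antiviral list for each library. Points are libraries (3 per group), horizontal marks the group means and bars ± 1 SD. Pml lies lower with shPML in each treatment, while the list means are 5.77 with shCtrl and 5.87 with shPML after IFNα.

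IFNα in shCtrl neurons raised antiviral effectors, interferon signalling components, antigen presentation genes and nucleic acid sensors, and lowered few genes. Of 14934 genes tested, 404 rose and 51 fell, and 268 and 10 of these changed at least 2-fold. Among the 67 antiviral genes tested 63 rose (65 adjusted over the list alone, where 1 fell), with a median log2 fold change of 3.87. Mx1, a dynamin-like GTPase that blocks incoming viruses, went from 0.254 ± 0.233 to 203 ± 34 CPM (SD, n = 3 each). Isg15, a ubiquitin-like protein that is attached to other proteins after interferon, went from 0.266 ± 0.25 to 132 ± 17.8 CPM, and Ifi44 from 0.0498 to 119 CPM. Zbp1, a sensor of Z-form nucleic acids, had no count in the mock-treated libraries and rose at least 302-fold. All 17 interferon-inducible GTPases tested rose, with a median of 7.10 (6.17 with 1 gene at its lower bound), though Gbp8 lost its call in 8 of 12 fits that left out a library. In that family Iigp1 went from 0.03 to 85.4 CPM.

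Signalling components and PML body proteins were induced in part. Of 20 interferon signalling genes 7 rose (9 adjusted over the list alone). They were led by the transcription factors Irf7 (79.3-fold, log2 fold change 6.31 ± 0.16 SE), Stat1 (15.6-fold), Stat2 (5.8-fold) and Irf9 (5.7-fold). All 21 antigen presentation genes tested rose, with a median of 2.02. H2-Q4, an MHC class I gene, rose 16-fold, and Nlrc5, the transactivator of MHC class I genes, 8.21-fold. Of 17 nucleic acid sensing genes 11 rose (14 adjusted over the list alone), among them the RNA sensors Ddx58 (RIG-I, 17.4-fold) and Ifih1 (MDA5, 15.7-fold). Of 30 PML nuclear body genes 5 rose (7 adjusted over the list alone), including Pml, Sp100 (31.5-fold), a permanent PML body component, and Sp110 (54.1-fold). Chemokine and inflammation genes rose in 6 of 18 cases (10 adjusted over the list alone), with Cxcl10, a T cell attractant, at 0.015 CPM in mock and 27.7 ± 14 CPM after IFNα. The estimated correlation left the camera calls of these 7 lists in place, with adjusted p from 6.4e-08 for the antiviral list to 0.0199 for chemokines.

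The remaining lists had few called members in shCtrl neurons. Genes with the largest falls included A830082N09Rik, a non-coding locus (log2 fold change −2.05 ± 0.31 SE), and Cfh, the complement inhibitor factor H (−1.32 ± 0.20 SE, 14 ± 3.45 to 5.59 ± 0.723 CPM). Cholesterol synthesis genes were lower as a list (median −0.13, camera adjusted p = 0.0228), with none of 21 called. That call was lost with an estimated correlation (adjusted p = 0.0847) and without IFNα-treated shCtrl replicate 2 (adjusted p = 0.0584). The stress effector Ddit3 was the called member of the unfolded protein and integrated stress response list (1.93-fold, 1 of 18). Among the p53 targets Eda2r was called (1.7-fold, 1 of 22, and adjusted over the list alone 5 rose and 2 fell). Eda2r was no longer called without mock-treated replicate 1 or IFNα-treated replicates 2 or 3 (adjusted p = 0.0695, 0.0631 and 0.0574). No member was called among the immediate early, axon injury, sympathetic identity, pan-neuronal, fibroblast and mural, endothelial, immune cell, cell cycle and mitochondrially encoded genes. The immune cell marker Lyz2 (log2 fold change −0.86 ± 1.16 SE) was called lower with a term in the fit for 4 libraries that stood apart from the other 8 (−0.79, adjusted p = 0.0126) and with no low-count filter (adjusted p = 0.00729). Dbh, which makes noradrenaline, was at 5180 ± 385 and 4940 ± 378 CPM. Among glia markers Cnp rose 1.72-fold and Glul fell (−0.42 ± 0.09 SE), with 16 of 18 not passing. The call of Glul was lost in 4 of 12 fits that left out a library. The mitochondrially encoded list did not pass (median −0.238, camera adjusted p = 0.0961, and 0.795 with an estimated correlation). It passed as lower without mock-treated shCtrl replicate 1 (adjusted p = 0.0159), IFNα-treated shCtrl replicate 3 (0.0211) or mock-treated shPML replicate 1 (0.0461), in the 8 libraries without those 4 (0.0159) and with no low-count filter (0.0312), and over all alternatives its adjusted p ran up to 0.795. The cell cycle list (adjusted p = 0.109) passed without mock-treated shCtrl replicate 3 (0.0403) or IFNα-treated shCtrl replicate 1 (0.0198), and with no low-count filter (0.00887), which also let the pan-neuronal list pass (0.0395). None of the 11 interferon genes had enough counts to be tested.

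Adjusted p-values of genes came from edgeR's quasi-likelihood test and those of lists from camera. The count of genes that fell depended on single libraries: it was 27 and 33 without mock-treated shCtrl replicates 2 and 3, and 26, 25 and 32 without IFNα-treated shCtrl replicates 1, 2 and 3. DESeq2 called 79 genes lower and no low-count filter gave 140.

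IFNα in shPML neurons induced the same groups. Of the genes tested 480 rose and 116 fell, 310 and 19 of them at least 2-fold. The antiviral list rose in 64 of 67 members (65 adjusted over the list alone, where 1 fell; median 4.07), the GTPases in 16 of 17 (17 adjusted over the list alone; median 6.15) and antigen presentation genes in 21 of 21 (median 2.17). Usp18, the protease that removes ISG15, rose 444-fold, Mx1 from 0.255 ± 0.212 to 204 ± 21 CPM (SD, n = 3 each), and Zbp1 at least 311-fold. Tgtp2, a GTPase, had no count in mock-treated shPML neurons and rose at least 341-fold. Irf7 rose 74.9-fold and Stat1 12.1-fold among 7 of 20 signalling genes (8 adjusted over the list alone). Ddx58 rose 18.8-fold among 14 of 17 nucleic acid sensors (15 adjusted over the list alone). Sp100 rose 24.6-fold among 6 of 30 PML body genes (adjusted over the list alone, 6 rose and 1 fell). Chemokine and inflammation genes rose in 5 of 18 cases (7 adjusted over the list alone), with Cxcl10 at 0.029 CPM in mock and 15.4 ± 6.44 CPM after IFNα and the immune checkpoint ligand Cd274 at 12.1-fold. These 7 lists held with an estimated correlation, with adjusted p from 5.55e-08 to 0.0324.

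Transcripts of the mitochondrial genome fell with IFNα in shPML neurons in 6 of 10 cases (7 adjusted over the list alone; camera adjusted p = 9.76e-09, but adjusted p = 0.134 with an estimated correlation). Mt-Nd1, a subunit of respiratory complex I, fell from 5180 ± 935 to 2450 ± 146 CPM (log2 fold change of mt-Nd1 −1.08 ± 0.14 SE), and mt-Co1, of complex IV, from 15700 ± 2710 to 9540 ± 877 CPM (mt-Co1 −0.72 ± 0.14 SE). The list had its members' median at −0.72, and at −0.74 in the 8 libraries other than a set of 4 that stood apart, and at −0.74 in those 4. Cholesterol synthesis genes were again lower as a list (median −0.11, camera adjusted p = 0.0342), with Dhcr7 the called member, and this was lost with an estimated correlation (adjusted p = 0.115). It was also lost without mock-treated replicate 3 or IFNα-treated replicates 1 or 2 of the shPML neurons (adjusted p = 0.0594, 0.0705 and 0.0569). Among p53 targets 4 rose and 1 fell of 22 (adjusted over the list alone, 5 and 1), led by Eda2r at 1.77-fold, and Ddit3 of the stress response list rose 1.89-fold, 1 of 18 (2 adjusted over the list alone). Of the immediate early genes Junb was called (1.52-fold, 1 of 13), and of 17 axon injury genes Crem rose and Flrt3 fell (2 and 1 adjusted over the list alone). The calls of Junb, Crem and Flrt3 were lost in 4, 4 and 10 of the 12 fits that left out a library, and that of Dhcr7 in 7. Of the p53 targets Sesn2, Mdm2 and Aen lost their calls in 10, 5 and 1. Glul fell and Cnp rose among 18 glia markers, and no member was called in the sympathetic identity, pan-neuronal, fibroblast and mural, endothelial, immune cell and cell cycle lists. The pan-neuronal list (camera adjusted p = 0.0994) passed without mock-treated shPML replicate 3 (adjusted p = 0.0454) and with no low-count filter (0.00341), a setting in which the lists of p53 targets (0.00375) and immediate early genes (0.0465) passed too. The fall of A830082N09Rik was −2.58 ± 0.32 SE. The count of 116 genes lower was 76 without mock-treated shPML replicate 2, and 54 and 53 without IFNα-treated shPML replicates 1 and 2. It was 197 with DESeq2 and 235 with no low-count filter.

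The interferon effects with the 2 shRNAs overlapped and had a similar size. Of the genes that rose, 360 were shared, against 13 expected of independent lists, and 26 of those that fell were shared against 0.396. Over the 665 genes called with either shRNA every gene had the same sign with both, and the fold changes followed each other across genes (Pearson's r = 0.963, slope 0.991), where genes are not independent replicates. In the test of the difference itself no gene passed with edgeR or DESeq2. At an unadjusted p under 0.05 there were 255 genes with edgeR, against 747 expected by chance, and 290 with DESeq2. Without single libraries in turn the count was 179 to 463, and it was 447, 402 and 463 without mock-treated shCtrl replicate 1 and mock-treated shPML replicates 2 and 3. In the 8 libraries that did not stand apart it was 1064 against 744 expected, with no gene called (smallest adjusted p = 0.492). With no low-count filter it was 609, and 5 genes passed as higher and 1 as lower. These were Gm25911, Gm24270, Lars2, Gm23935 and CT010467.1, and Bc1. They were chosen after their values were seen, and in the planned fit the most counted of them, CT010467.1, Gm23935 and Lars2, had an adjusted p of 1. CT010467.1 is annotated as ribosomal RNA, and these 3 genes together took 2.3 to 10.9% of a library's counts.

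**Figure D2:**
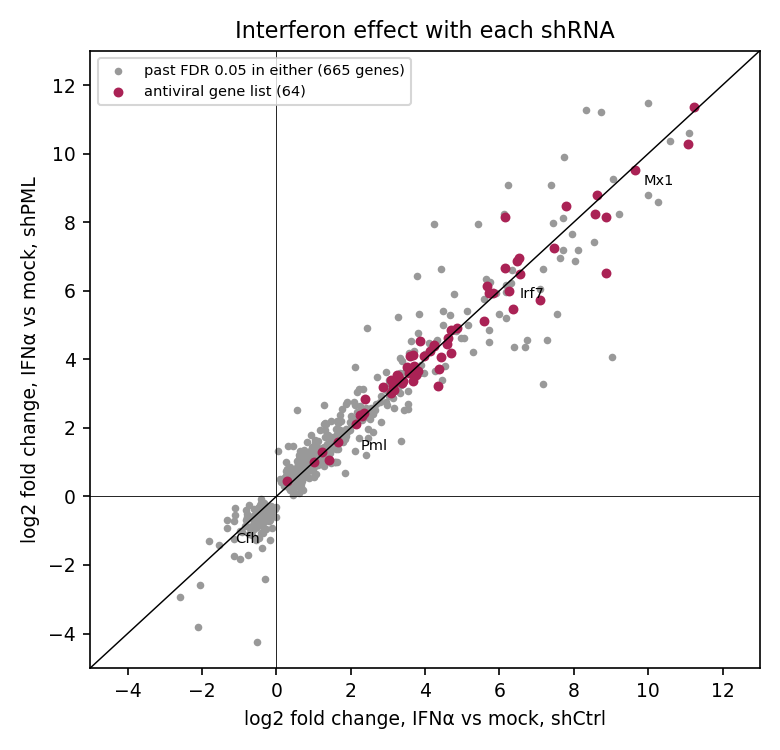
Log2 fold change by IFNα with shCtrl (x axis) and with shPML (y axis) for the 665 genes called with either shRNA; red points belong to the antiviral list and the line marks equal change. Points lie along the line (slope 0.991). Fitted values of genes with few or no counts in mock-treated libraries depend on the prior count.

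Over 359 genes raised at least 2-fold by IFNα on average, the median interaction was 0.08 on the log2 scale, or 0.07 over the 334 genes with counts in all groups. The response was larger with shPML for 204 genes and smaller for 155. At an unadjusted p under 0.05 there were 18, with 17.9 expected of evenly spread p-values, and none passed the adjusted test in edgeR. Over all 14934 genes tested only 255 reached that p, against 747 expected. The 359 induced genes thus held a larger share of small p-values than all genes, and the cause was not tested. In the 8 libraries that did not stand apart the count over all genes was 1064, against 744 expected. The low count of 255 thus depends on the libraries fitted and does not show that differences are absent. The median interaction was −0.05 in the 4 libraries that stood apart, 0.13 in the other 8, and 0.19 without mock-treated shPML replicate 3. For 107 of the 334 genes the 95% interval excluded a 2-fold difference in either direction, and for the rest such a difference was not excluded. In counts simulated independently for each gene, with the induction of every such gene lowered 1.5-fold, the median was −0.49. Of single induced genes lowered 2-fold 13.4% were called. The score of the antiviral list was 1.51 ± 0.0679 and 1.54 ± 0.109 in mock-treated shCtrl and shPML neurons and 5.77 ± 0.119 and 5.87 ± 0.0731 after IFNα (SD, n = 3 each). Exact permutation tests, two-sided, gave p = 0.7 in mock and 0.3 after IFNα, where 3 libraries against 3 cannot go below 0.1. By list, the interferon effect differed in the mitochondrially encoded genes (camera adjusted p = 9.95e-15, with median −0.57 and none called, 4 adjusted over the list alone). That call was lost with an estimated correlation (adjusted p = 0.348). Other lists passed only in fits that left out a library. The cell cycle list (adjusted p = 0.214) did so without shCtrl replicate 3 or shPML replicate 1 of the mock-treated neurons (0.0396 and 0.00136) and without replicate 1 of either IFNα-treated group (0.00236 with shCtrl, 0.0437 with shPML). Glia markers (adjusted p = 0.305) did so without mock-treated shCtrl replicate 3, mock-treated shPML replicate 1 or IFNα-treated shPML replicate 1 (0.0407, 0.00585 and 0.0311), and immune cell markers (adjusted p = 0.454) without IFNα-treated shCtrl replicate 3 or mock-treated shPML replicate 3 (0.00936 and 0.0409).

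Between the shRNAs, genes differed in both directions in mock-treated neurons. Rises and falls are relative to shCtrl, so either hairpin could be behind them, and 3′ UTR sequences given below bear on this. Of the 14934 genes tested 498 were higher and 476 lower with shPML than with shCtrl, 83 and 71 of them at least 2-fold. At that share few genes of a list of 67 would be called. A low count in the interferon lists thus does not show that they were spared. The largest rises were in Ccng1, the p53 target cyclin G1 (54.3 ± 3.93 to 341 ± 35.8 CPM, SD, n = 3 each; log2 fold change of Ccng1 2.65 ± 0.14 SE), Isoc1 (80.7 ± 3.34 to 459 ± 42.8 CPM, 5.69-fold), Adcy1, an adenylyl cyclase (4.96-fold), and the kainate receptor gene Grik3 (4.09-fold). Among the largest falls were Arfgef3 (284 ± 18.7 to 82.8 ± 18.1 CPM, log2 fold change −1.78 ± 0.14 SE) and Rgs17, a regulator of G protein signalling (−1.69 ± 0.12 SE). Of the PML body genes 5 of 30 fell, including Pml and Ubn1, a subunit of the HIRA histone chaperone (−1.18 ± 0.10 SE, 53.4 ± 3.32 to 23.6 ± 1.41 CPM), while the list as a whole did not pass (camera adjusted p = 0.447). Of 67 antiviral genes 1 was called, Ifi27l2a, from 0.167 to 0.598 CPM, and none adjusted over the list alone. Of 20 signalling genes 1 was called, the phosphatase Ptpn1 (log2 fold change 0.32 ± 0.08 SE; 3 adjusted over the list alone), and of 17 GTPases Gbp9, at 2.05 and 3.63 CPM. Of the antigen presentation, nucleic acid sensing and chemokine genes none was called, though Nfkb1, of the chemokine and inflammation list, was called higher in the 8 libraries (0.41, adjusted p = 0.027). Leaving out a library in turn ended the calls of Ifi27l2a, Ptpn1 and Gbp9 in 3, 4 and 11 of 12 fits. The calls of Atrx and Topors, which were among the 5 PML body genes that fell, ended in 4 and 3.

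A few stress and neuronal genes were also called in mock-treated neurons. Atf4, the transcription factor of the integrated stress response, fell from 239 ± 35.5 to 144 ± 17.5 CPM (log2 fold change of Atf4 −0.73 ± 0.12 SE) and its target Trib3 fell too, 2 of 18 in that list (3 adjusted over the list alone; camera adjusted p = 0.0113, but adjusted p = 0.116 with an estimated correlation). Ednrb, the endothelin receptor B, fell from 212 ± 43.7 to 74.4 ± 19.9 CPM (−1.51 ± 0.21 SE) and was the called member of the 18 glia markers. That list's median was −0.46 (camera adjusted p = 0.0126, but adjusted p = 0.892 with an estimated correlation). The glia call was also lost without mock-treated shCtrl replicate 1 or shPML replicates 2 or 3 (adjusted p = 0.0547, 0.0514 and 0.052). Among 22 p53 targets 2 rose, Ccng1 and Ei24 (1.84-fold), and 2 fell (3 adjusted over the list alone), among them Trp53inp1 (−0.73 ± 0.13 SE). Ldlr, the LDL receptor, rose 2.22-fold while Fdft1, squalene synthase, fell (−0.51 ± 0.09 SE), 1 each of 21 cholesterol genes. Slc18a2, the vesicular monoamine transporter, fell (−0.55 ± 0.09 SE, 811 ± 90 to 555 ± 25.5 CPM) as the called member of 27 sympathetic identity genes. Of 28 pan-neuronal genes 4 rose, by 1.23- to 1.47-fold, including Nefh and Nefl, neurofilament proteins, and these calls were each lost in 4 to 11 of the 12 fits that left out a library. The cytokine receptor Lifr rose 1.47-fold and Sox11 was the other called member of 17 axon injury genes (2 rose and 1 fell adjusted over the list alone). Aurka was called among 20 cell cycle genes, at 1.95 and 3.69 CPM. Trib3, Sox11 and Aurka were no longer called in 4, 10 and 10 of those 12 fits, nor in 5 of them Sesn2, the other p53 target that fell. No member was called among the immediate early, fibroblast and mural, endothelial, immune cell and mitochondrially encoded genes. The mitochondrially encoded list (camera adjusted p = 0.242) passed as higher without mock-treated shPML replicate 2 (adjusted p = 0.00565) and with no low-count filter (0.0378). Lyz2, an immune cell marker, was called lower with the split of the libraries as a term (−0.67, adjusted p = 0.0215).

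The counts in mock-treated neurons depended on single libraries. Without shCtrl replicates 2 and 3 there were 226 and 253 genes higher and 251 and 298 lower, and without shPML replicates 1 and 2 there were 301 and 307 higher, with 316 lower without shPML replicate 1. A fit of only the 6 libraries gave 245 higher and 270 lower.

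In IFNα-treated neurons 377 genes were higher and 469 lower with shPML than with shCtrl, 56 and 51 of them at least 2-fold. Of the 67 antiviral genes 2 were higher with shPML and none was lower. With 846 of all 14934 genes called, few would fall in a list of 67 in any case. This count thus does not show that the list was spared. Rsad2, the antiviral enzyme viperin, was at 76.2 ± 20.1 CPM with shCtrl and 185 ± 10.4 CPM with shPML (SD, n = 3 each; log2 fold change 1.28 ± 0.17 SE, adjusted p = 0.000643), and Phf11d at 27.2 ± 7.46 and 52.5 ± 4.32 CPM (0.95 ± 0.19 SE). Nlrc5 was also higher, at 47.3 ± 4.29 and 83.5 ± 5.49 CPM (log2 fold change of Nlrc5 0.82 ± 0.16 SE), and Erap1, which trims peptides for MHC class I, was lower (−0.56 ± 0.10 SE), 1 each of 21 antigen presentation genes (2 and 1 adjusted over the list alone). Phf11d was no longer called without IFNα-treated shCtrl replicate 1 or shPML replicate 2 (adjusted p = 0.0655 and 0.054), nor Nlrc5 without shCtrl replicate 1 (adjusted p = 0.0541). The antiviral list as a whole had a median of 0.07 (camera adjusted p = 0.311). It passed in the 8 libraries (adjusted p = 0.0469) and without IFNα-treated shCtrl replicate 3 (adjusted p = 0.0384). None of the 17 GTPases, 17 nucleic acid sensors (1 rose and 1 fell adjusted over the list alone) and 18 chemokine genes was called, with Irgm1 at 288 ± 16.3 and 318 ± 34.7 CPM. Ptpn1 was the called member of 20 signalling genes (2 rose and 1 fell adjusted over the list alone).

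In the fits that left out a library the call of Ptpn1 ended in 2 of 12.

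Outside the interferon lists the genes resembled those of mock-treated neurons. Ccng1 rose 5.42-fold, Isoc1 4.89-fold and Ei24 1.94-fold, and Caln1 and Cdh22, a cadherin, were among the largest rises with 0.146 and 0.448 CPM in the controls and 1.79 and 2.68 CPM with shPML. Myh10, non-muscle myosin IIB, fell from 145 ± 9.27 to 45.7 ± 2.62 CPM (log2 fold change of Myh10 −1.66 ± 0.09 SE), Arfgef3 by −1.60 ± 0.14 SE, Ednrb by −1.50 ± 0.21 SE and Slc18a2 by −0.55 ± 0.09 SE. PML body genes were lower as a list, with Pml, Ubn1 (−1.09 ± 0.10 SE), Atrx and Usp7 called of 30 (7 adjusted over the list alone). The camera adjusted p of that list was 0.0246, but adjusted p = 0.307 with an estimated correlation. Pml, the target of the shRNA, is a member, and the list was not tested without it. The calls of Atrx and Usp7 were lost in 4 and 3 of the 12 fits that left out a library. The list's adjusted p was 0.0827 in the 8 libraries, and 0.0843 and 0.0605 without shCtrl replicate 3 and shPML replicate 2 of the IFNα-treated neurons. Integrated stress response genes were lower as a list with none of 18 called (median −0.17, camera adjusted p = 0.0246, but adjusted p = 0.233 with an estimated correlation). That adjusted p was 0.0843 without IFNα-treated shCtrl replicate 3. Mitochondrially encoded genes were lower too (median −0.32, 1 of 10 called, mt-Nd1, lost in 4 of those 12 fits, 2 adjusted over the list alone; camera adjusted p = 0.022, but adjusted p = 0.862 with an estimated correlation, 0.317 in the 8 libraries and 0.131 without IFNα-treated shCtrl replicate 3). Ldlr rose 2.14-fold and 2 of 21 cholesterol genes fell (2 rose and 2 fell adjusted over the list alone). The 2 that fell, Hmgcr and Fdft1, lost their calls in 8 and 4 of those 12 fits. Of 27 sympathetic identity genes 1 rose and 2 fell (1 and 3 adjusted over the list alone), of 28 pan-neuronal genes 1 rose (3 rose and 1 fell adjusted over the list alone), of 22 p53 targets 2 rose and 1 fell, and of 17 axon injury genes 1 fell (2 adjusted over the list alone). Among these, Insm1 and Dbh (sympathetic), Nefl (pan-neuronal) and Il6st (axon injury) lost their calls in 4, 7, 4 and 5 of the 12 fits. Besides Ednrb no glia marker was called, and none of the immediate early, fibroblast and mural, endothelial, immune cell and cell cycle genes. The glia list (camera adjusted p = 0.132) passed without shCtrl replicate 2 or shPML replicate 3 of the IFNα-treated neurons (adjusted p = 0.00958 and 0.0309), and the fibroblast and mural list (adjusted p = 0.51) without that shPML replicate 3 (0.0318).

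The shRNA effects in the 2 treatments overlapped. Of the genes that rose 284 were shared, against 12.6 expected of independent lists, and of those that fell 325 against 14.9. Over the 1211 genes called in either treatment 1205 had the same sign in both (across genes, Pearson's r = 0.894, slope 0.856). The counts in IFNα-treated neurons depended on single libraries: without shCtrl replicates 1 and 2 there were 121 and 162 higher and 215 and 240 lower, and without shPML replicates 1 and 2 there were 148 and 141 higher and 236 and 210 lower.

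**Figure D3:**
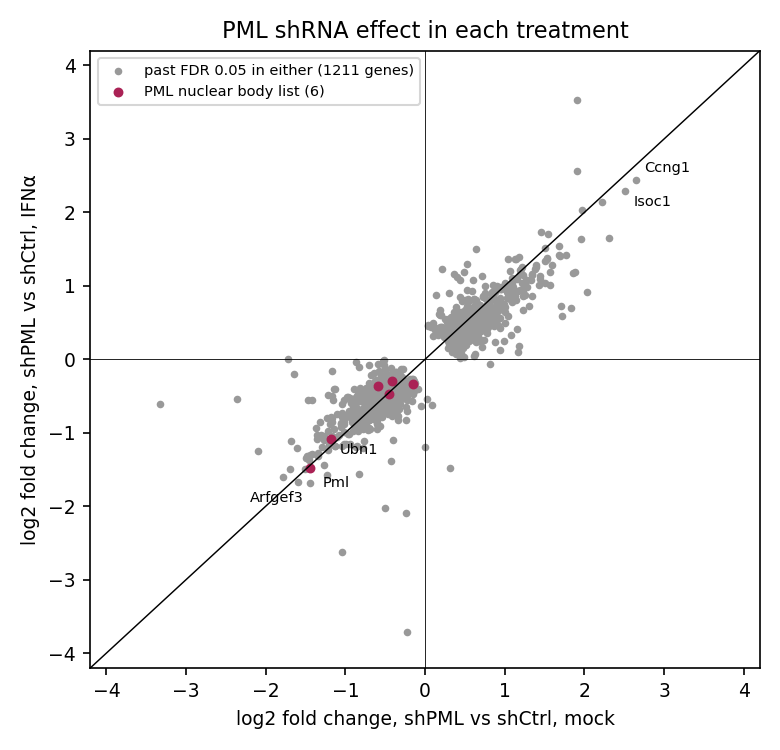
Log2 fold change between shPML and shCtrl in mock-treated (x axis) and IFNα-treated neurons (y axis) for the 1211 genes called in either treatment; red points belong to the PML nuclear body list and the line marks equal change. The slope across genes is 0.856, and Ccng1, Isoc1, Arfgef3, Ubn1 and Pml are named.

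In each group 1 library stood apart from the other 2, and the labels name no reason for it. It was replicate 3 in every group but mock-treated shCtrl, where it was replicate 1. These 4 libraries lay on 1 side of the first component of the deviations from group means, which held 48.1% of that variation. Immune cell markers such as Lyz2, a lysozyme of myeloid cells, were higher in them, with 33 to 53 CPM summed over the 14 markers tested against 12.6 to 17.6 CPM in the other 8. Since each group held 1 of the 4, the comparisons were repeated within each set. Genes were called in the 8 alone and their signs read in the 4, which took no part in the calls, where chance gives 50%. For IFNα 612 of 632 genes with shCtrl (96.8%) and 906 of 958 with shPML (94.6%) had the same sign in the 4, and between the shRNAs 1747 of 2084 in mock (83.8%) and 1735 of 1888 after IFNα (91.9%). Among genes at an unadjusted p over 0.5 in the 8 these shares were 50.8, 52.5, 52 and 54.3%. Pml was lower with shPML by −1.55 and −1.42 in the 4 and by −1.36 and −1.53 in the 8, in mock and after IFNα. With the split as a term, IFNα raised 693 and lowered 268 genes with shCtrl and raised 848 and lowered 447 with shPML, and all 455 and 596 planned calls were among them. Against shCtrl, 1079 genes were then higher and 1065 lower with shPML in mock, and 1006 and 1083 after IFNα. All 974 and 846 planned calls were among them. The interaction stayed at 0 in edgeR, with 557 genes at an unadjusted p under 0.05, and at 0 in the 8 alone, with 1064 such genes, where 744 are expected by chance.

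**Figure D4:**
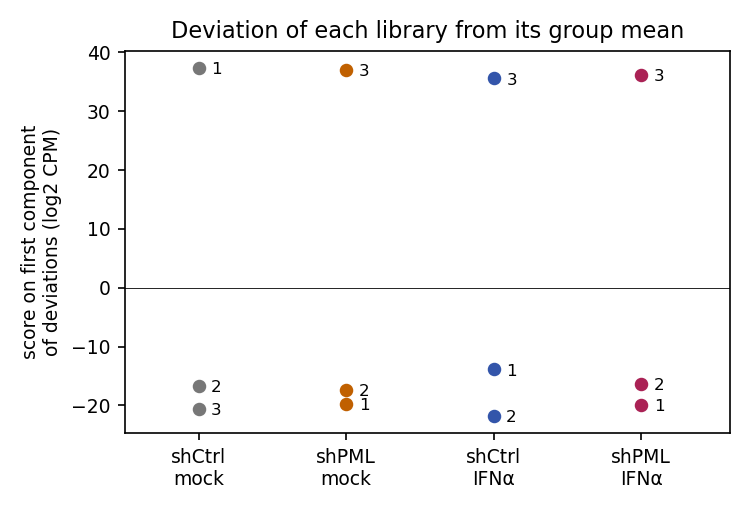
Score of each library on the first component of the deviations of log2 CPM from the group means, by group, with the replicate number beside each point. The 4 libraries at the top lie 49.5 units from the nearest other library, and the next largest gap is 2.45.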

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

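The comparison of mitochondrial rRNAs with mRNAs and the refit on 8 libraries were chosen after the result was seen. The mitochondrially encoded mRNAs were picked out because the effect of IFNα on them as a list differed between the shRNAs in the interaction test, with a camera adjusted p of 9.95e-15 at a preset correlation. Their share of counts was 3.58 ± 0.139% and 2.9 ± 0.448% in mock-treated and IFNα-treated shCtrl neurons, and 3.89 ± 0.717% and 2.23 ± 0.167% in shPML neurons (SD, n = 3 each). No single gene passed over all genes, 10 of 10 members had a negative interaction, and 4 passed adjusted over the list alone. The members move together, with an estimated correlation of 0.784, and with that correlation the adjusted p was 0.348, so a difference between the shRNAs is not shown beyond the spread of these libraries.

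In shCtrl neurons alone the list's median with IFNα was −0.238, and 0.01 in the 4 libraries that stood apart. Its adjusted p was 0.0961, 0.0159 in the 8 other libraries and 0.795 with an estimated correlation, so a fall there is neither shown nor excluded.

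The fall itself, in IFNα-treated against mock-treated shPML neurons, was weighed against technical explanations. The 4 libraries that stood apart were not its whole cause, since the list's median fell to −0.74 in the 8 other libraries. A lower yield of mitochondrial RNA of every kind was set against the mitochondrial rRNAs mt-Rnr1 and mt-Rnr2. Their mean log2 fold change was 0.39, which lies 1.13 above that of the mRNAs. The SE of this gap, 0.14, treats genes as independent, though the mRNAs move together. Mt-Rnr1 rose by 0.72 ± 0.18 SE in shPML neurons, where mt-Rnr2 was at 0.06 ± 0.19 SE. In shCtrl neurons mt-Rnr1 was at 0.41 ± 0.18 SE, not called. Ribosomal RNA counts varied between shPML libraries, with CT010467.1 from 1.1% (mock-treated replicate 1) to 4.45% (IFNα-treated replicate 1). In replicates 2 and 3 that share was 2.05 and 1.44% in mock and 2.03 and 1.75% after IFNα. There mt-Rnr1 was at 1715 and 2378 CPM in mock and 3504 and 3501 CPM after IFNα. Mt-Rnr2 was at 1402 and 2124 CPM in mock and 1911 and 2154 CPM after IFNα. These values argue against a lower yield of mitochondrial RNA of every kind as the whole cause in shPML neurons. The PML shRNA alone does not account for the fall, since both groups carry it. A lower yield of mitochondrial RNA as a part of the fall and an effect of IFNα, with or without a part of the PML shRNA in its size, stay open.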

How the results depend on the processing

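The fits with the library split as a term and on the 8 other libraries were chosen after the data were seen. No result changed direction past its threshold under any setting run. Pml stayed lower with shPML, by −1.58 to −1.31 in mock and −1.63 to −1.38 after IFNα without each library in turn. RSEM expected counts and the other scaling kept every count of calls within 1.5 times, and that scaling moved the median of all genes by at most −0.0115. With no low-count filter IFNα lowered 140 genes (shCtrl) and 235 (shPML) and the interaction called 5 higher and 1 lower. At the same log2 fold change of −1.44, Pml in mock had an edgeR adjusted p of 1.86e-14 without the filter and 0.000405 with it. Calls gained only without the filter may thus rest on how the spread was fitted, which was not tested. DESeq2 gave 79 and 197 lower with IFNα. Only the 6 libraries compared gave 31 and 66 lower with IFNα, and 245 higher and 270 lower with shPML in mock, with fewer samples behind the spread. With the split as a term IFNα gave 693 and 268 (shCtrl) and 848 and 447 (shPML), and shPML 1079 and 1065 in mock and 1006 and 1083 after IFNα. The 8 libraries gave 111 and 334 lower with IFNα, and 1123 and 964 with shPML in mock and 842 and 1047 after IFNα. Apart from the fits of 6 libraries, the cause was not tested. Without each library in turn, IFNα lowered 25 to 51 genes (shCtrl) and 53 to 134 (shPML). With shPML 226 to 529 genes were higher and 251 to 491 lower in mock, and 121 to 449 and 210 to 530 after IFNα. The median interaction of induced genes ran from −0.01 to 0.19. The interaction stayed at 0 genes in each of those fits of edgeR, with 179 to 463 at an unadjusted p under 0.05. That count was 557 with the split as a term, 1064 in the 8 libraries and 609 with no low-count filter.

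Replicate numbers did not pair the libraries throughout. Same-numbered libraries had correlations of deviations from −0.452 to 0.616 (median 0.223, against −0.068 for different numbers), with 12 of 18 over 0.1. Of 12 libraries 6 correlated best with their own number. Every negative value of a same-numbered pair involved a mock-treated shCtrl library. Outside that group same-numbered pairs ran from 0.187 to 0.616 and different-numbered pairs from −0.479 to 0.381. Mock-treated shCtrl replicate 1 correlated with replicate 3 of the other groups at 0.533 to 0.582. For mock-treated shCtrl replicate 3 these correlations were −0.437 to −0.362. The numbers thus followed the split of 4 libraries in every group but this one. A block by number therefore does not fully take out that split. Whether the numbers mark a shared batch, with numbers 1 and 3 exchanged in this group, was not tested. With the replicate number as a block, IFNα gave 418 and 48 genes (shCtrl) and 503 and 114 (shPML), and shPML 464 and 485 in mock and 381 and 453 after IFNα. The interaction stayed at 0 with the block, with 295 genes at an unadjusted p under 0.05. Of the calls of named genes, 10 were lost with RSEM counts, 8 with no filter, 23 with only the 6 libraries and 6 with the block. An estimated correlation ended 9 list calls. Depth sets the lower bounds given for folds against groups with no count, such as Zbp1 at least 302-fold.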

Other observations

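The tests of immune cell RNA and of near-identical copies, in the form given here, the choice of sequence sites counted per gene, and the sorting of draws by balance came after the results were seen. The 4 libraries that stood apart differed from the other 8 in 3533 genes (1805 higher, 1728 lower, edgeR), a count that follows from sorting libraries by this difference and is given as a description. Immune cell markers were higher in 12 of 14 cases (median 1.75, camera adjusted p = 6.35e-11, and adjusted p = 0.00295 with an estimated correlation), and fibroblast and mural markers in 10 of 17 (2.53e-06, but adjusted p = 0.33 with an estimated correlation). Mmp12 and Gpnmb, genes of activated macrophages, were at 8.79 to 14.8 and 16.2 to 28.5 CPM in the 4 against 0.279 to 1.93 and 2.4 to 4.12 CPM in the 8. The transcriptional inhibitors Id1 to Id4 were lower, with Id1 at 2.96 to 4.58 against 18.4 to 30.3 CPM. Axon injury, chemokine and nucleic acid sensing genes were higher as lists (camera adjusted p = 0.0114, 0.0114 and 0.0461, but adjusted p = 0.133, 0.33 and 0.33 with an estimated correlation). These genes were chosen after their values were seen.

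Neither more immune cell RNA nor read assignment accounts for the whole split. Added cells would dilute the genes of other cells alike. The pan-neuronal median was −0.08 ± 0.064 (SE), and 599 genes fell by more than −0.27, which is that median and 3 of its SE, in a test against this bound (adjusted p under 0.05). When the genes were parted into 2 equal sets, each set put the same 4 libraries apart. Rps2-ps10, a pseudogene, was at 0.13 to 1.4 CPM in the 4 and 99.9 to 128 CPM in the 8, and the ribosomal protein gene Rpl26 at 62.1 to 67.9 and 5.63 to 7.2 CPM. With RSEM expected counts their log2 differences shrank from −7.48 to −2.70 and from 3.39 to 0.67. That of Rps3a3, another pseudogene, grew from −5.87 to −9.06. Among the genes called at 4-fold 9.15% were pseudogenes against 3.13% of those tested, so read assignment may have a part. But 86.4% of the 3533 called genes were also called with the same sign with RSEM counts, which share out reads that match several places. The difference did not follow the annotated exon length of genes (Spearman's rho 0.032 across genes). Gene counts do not show coverage along a transcript, so this does not exclude RNA degradation. What stays open is RNA degradation or a batch of culture or library preparation, with more immune cells in it as a part. No biological explanation was tested, since the labels name no such groups.

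Genes changed between the shRNAs shared short 3′ UTR sequences, which makes shRNA off-target repression a candidate explanation for many of them. Genes lower with shPML were marked by GACAATG in mock (z = −14.4, shuffles reaching −4.92) and by the overlapping ACAATGA after IFNα (z = −14.4, shuffles reaching −5.09), as seed pairing of the PML hairpin would give. Genes higher with shPML were marked by ATATCAC (z = 14.7 in mock and 14.2 after IFNα, shuffles reaching 4.93 and 5.12), as repression by the control hairpin, relieved in shPML neurons, would give. At least 1 of the leading sequences (5 overlapping ones on the lower side, 4 on the higher) lay in 73.3 and 76.7% of the genes called lower against 28.1% of all searched, and in 56.1 and 53.3% of those called higher against 22.4%. Effects of PML loss remain open, for the 121 and 106 genes lower and 212 and 170 higher without such a sequence and for the others too, since a single PML shRNA was used and the hairpin sequences were not used here.

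In the IFNα contrasts the same sequences had positive z values of 1.34 to 6.07, opposite in sign to the shRNA contrasts on the lower side. TATCACA with shCtrl (6.07) and GACAATG with shPML (5.16) lay past the 5.12 that shuffles reached in the shRNA contrasts. Both groups of an IFNα contrast carry the same hairpin. A z past the shuffles is therefore not specific to a difference in hairpin, and what lies behind these values was not tested. Of the named genes called lower with shPML and searched, 14 of 22 had a sequence of the lower side, and of those called higher 13 of 21 had one of the higher side. Rgs17 had 11 occurrences of the sequences of the lower side, Arfgef3 9, Myh10 6, Ubn1 5 and Ednrb 4. Atf4, Dbh, Hapln4, Pml, Sesn2, Slc25a34, Trib3 and Usp7, all lower, had none. Isoc1 had 9 of those of the higher side, Ccng1 4, Grik3 4, and the interferon-stimulated genes that were higher with shPML after IFNα, Nlrc5, Phf11d and Rsad2, had 3, 3 and 1. Aurka, Cdh22, Elavl3, Ifi27l2a, Insm1, Nefh, Nefl and Sox11, all higher, had none, and Cdh22 and Gbp9 had more of the lower side (1 and 2) than of the higher (0 and 1).

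Other splits of the 6 libraries of each comparison were counted. The real splits gave 455, 596, 974 and 846 genes for IFNα with shCtrl, IFNα with shPML, shPML in mock and shPML after IFNα, and the highest of the other splits gave 0 in each. With 10 splits per comparison, 1 of them the real one, the share cannot go under 0.05. For the interaction, 255 genes had an unadjusted p under 0.05, and 74 of 100 draws of shRNA labels within each treatment, the real one included, gave as many, with a highest other draw of 2760. These draws do not test chance, since 80 of the 99 others moved part of the shRNA effect, of the split of the 4 libraries, or of both into the interaction. Both are structures of the samples that give high counts. Draws that moved most of the shRNA effect and kept the 4 balanced gave 1536 to 2440 genes, and draws that moved most of the split and kept the shRNAs balanced gave 1685 to 2575. The 19 draws that kept both balanced gave 73 to 389 genes, 6 of them at least 255, with the shRNA effect adding to the spread within groups. Whether chance gives the count of 255 stays open.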
